A study of Gallus gallus with 16 samples.

How the data were processed

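Gene expression was measured in pineal glands of male Rhode Island Red chicks aged 1 week on 16 two-channel cDNA arrays. Each array carried 1 RNA pool of 5 to 6 glands. Per the labels, the pineal RNA was amplified and labelled with the Cy3-type dye, and a reference made of equal amounts of all 16 pools was labelled with the Cy5-type dye on every array, so there was no dye swap. The values used, taken as log2 values, are the log ratios of the 2 channels for each probe and array as deposited by the authors. The background correction and the normalization that the authors applied before are not given in the sources used here. The log base is not stated either: the ratios were taken as log2, because the largest size in the table, 10.1, is a fold of 1061 on that scale and would be 23190 as a natural log. If the base was another, every size on the log scale changes by 1 factor, while tests and counts of genes stay as they are. Which channel is the numerator also stays unknown, so "higher" and "lower" refer to the deposited ratio. If the reference was the numerator, every sign in the text turns together, and sizes, counts and the relations between genes and comparisons do not change.

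The direction was examined through the reference, which holds all 16 pools in equal amounts: with the sample as numerator, the mean ratio of a gene must fall as its variance between groups grows. The slope of the mean on that variance across 12532 genes was -0.0314, but it was 0.00844 without the paradigm 3 arrays, and the direction was left open. Arrays appeared centred: their medians ran from -0.0439 to 0.0518. The arrays of the long day had medians of 0.0256 and 0.0103, and those of their dark controls 0.0518 and 0.0197. Medians were -0.0111 and -0.0168 for early-night light, and -0.00281 and -0.0439 for its dark controls. For late-night light they were -0.00827, 0.00217, 0.0230 and 0.00119, and for its dark controls 0.00371, -0.00311, 0.00615 and 0.00649. The lowest correlation between any pair of arrays was -0.290.

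The table held 15769 probes. Left out were 160 control spots, recognised by 5 names that each occur on 32 spots (plant genes and chicken genomic DNA), which left 15609. Of these, 9628 had 1 gene symbol in the platform annotation, 0 had several, and 5981 had none there and kept their probe names. Of 9629 annotated probes, 9486 had a gene ID present in the reference gene table, and 0 of those carried another current symbol. A gene was the mean of all probes with its symbol; 1918 genes had more than 1 probe. Genes needed a value on at least 2 arrays of every group, which removed 159 and left 12532 for testing, 6660 with a symbol and 5872 unnamed probes. Between 15554 and 15603 probes were measured per array. The files hold no intensities, so signal over background is unknown, and the number of arrays limits the precision.

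Groups came from the labels. Paradigm 1 has 4 pools of late-night light and 4 dark controls, paradigm 2 has 2 pools of early-night light and 2 dark controls, and paradigm 3 has 2 pools of a long day and 2 dark controls. Differences between group means were fitted with limma 3.58.1 in R 4.3.3 (lmFit, contrasts.fit and eBayes with a constant prior) over all 16 arrays with 1 mean for each of the 6 groups, leaving 10 residual degrees of freedom plus 3.33 from the prior. Genes were called at a Benjamini-Hochberg adjusted p under 0.05 within a comparison. The comparisons were late-night light, early-night light and the long day against their own dark controls, the mean of the last 2 (light at ZT14), time of day in the dark controls, the differences between light effects, and the ZT14 dark controls of paradigm 3 against those of paradigm 2. One comparison, late-night light against light at ZT14, was added after the data were seen. Errors given with ± are standard errors from this fit unless named as SD. Pools hold different glands, so p-values measure the spread between pools, averaged over all 6 groups and not that of the compared groups alone. The SD of the residuals was 0.379 to 0.471 on the arrays of paradigm 3 and 0.224 to 0.258 on those of paradigm 2. No repeat of a paradigm is labelled, so the spread between repeats is not measured.

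Before the data were examined, 26 gene lists were fixed: core clock, melatonin synthesis, phototransduction, pineal transcription factors, immediate early genes, cAMP and calcium signalling, sterol synthesis, fatty acid synthesis, heat shock proteins, endoplasmic reticulum folding, ribosomal proteins, oxidative phosphorylation, glycolysis, thyroid and photoperiod genes, cell cycle, interferon response, and markers of 10 other cell types. Lists were tested with camera at a preset correlation of 0.01, adjusted over the 26 lists of a comparison. Named genes followed a rule fixed at the same time: the 8 largest differences in each direction among called genes with a symbol and no overlap between the compared groups, up to 4 called members of each list, 7 measured clock, melatonin and early genes always, and the 10 smallest p-values where fewer than 10 genes with a symbol passed. Other genes named by their counts of 5 or fewer, the unnamed probes and the genes singled out in the closing section were chosen after their values were seen.

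The fit was tested on simulated data for 12532 genes, with independent normal noise scaled to the spread of each gene and of each array. This noise holds no correlation between genes, no component shared by arrays and no extreme single values. False calls and recovery in the real data may therefore be less favourable. In 20 data sets without any change, limma called on average 0 genes for late-night light, 0 for early-night light, 124.2 for the long day (at most 188), 0.35 for time of day and 0.55 for light at ZT14. With 200 genes changed by 1 on the log2 scale, 61.2% were recovered for late-night light, 13.1% for early-night light, 39.3% for the long day, 62.0% for time of day and 62.1% for light at ZT14. With changes of 2, these shares were 96.1%, 88.6%, 90.1%, 96.8% and 95.7%, and with changes of 0.5 they were 0.2%, 0%, 7.8%, 0.5% and 0.7%. With changes of 1 and of 2, false calls averaged 211 and 306.2 for the long day, 43.6 and 60 for light at ZT14, 19.6 and 29 for time of day, 1.6 and 2.6 for late-night light and 0.8 and 2.2 for early-night light. The mean estimate for a change of 1 was 1.00 for late-night light.

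Alternatives were centring each array on its median, quantile normalization, other filters on missing values and on noisy genes, single probes in place of genes, a prior with trend and robust fitting, array weights, only the arrays compared, adjusted p under 0.10, a fold minimum of 1.5, each replicate left out, the pool number or the slide number series as a block, other control groups, and estimated correlations or fry for the lists. Added after the data were seen were arrays scaled to 1 standard deviation, the paradigm 3 arrays left out, only the first slide series, and control spots kept. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.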

Results

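The avian pineal gland holds its own circadian clock and its own photoreceptor proteins, and secretes melatonin at night. The arrays compared pineal glands of chicks that received light at night with those of chicks left in darkness, in 3 paradigms to which birds were assigned at random, with 25 birds in each light group. Lights-on of the cycle of 12 h light and 12 h dark is ZT0. In paradigm 1, birds received 2 h of light from ZT22 to ZT24 (late-night light) and glands were taken at ZT0, with 4 pools of light birds and 4 of controls. In paradigm 2, birds received 2 h of light from ZT12 to ZT14 (early-night light) and glands were taken at ZT14, with 2 pools of each. In paradigm 3, birds lived in a long day, given as 15 h light and 9 h dark in one label and as 17 h light and 7 h dark in another, and glands were taken at ZT14, with 2 pools of each. Every value is a deposited log ratio between a pineal pool and the common reference, taken as log2, and a difference is the light group minus its dark controls. Higher means a higher deposited ratio, since the labels do not name the numerator, and with the opposite numerator all signs turn together.

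The 16 arrays differed in how widely their values spread. The SD over probes lay between 0.820 and 1.08 on the 4 arrays of paradigm 3, between 0.391 and 0.510 on those of paradigm 2 and between 0.248 and 0.546 on those of paradigm 1. Arrays of paradigm 3 correlated across genes at 0.507 to 0.600 with one another, light and dark alike, and at -0.290 to -0.0677 with those of paradigm 1. Genes are not independent replicates, so these correlations carry no p.

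**Figure D1:**
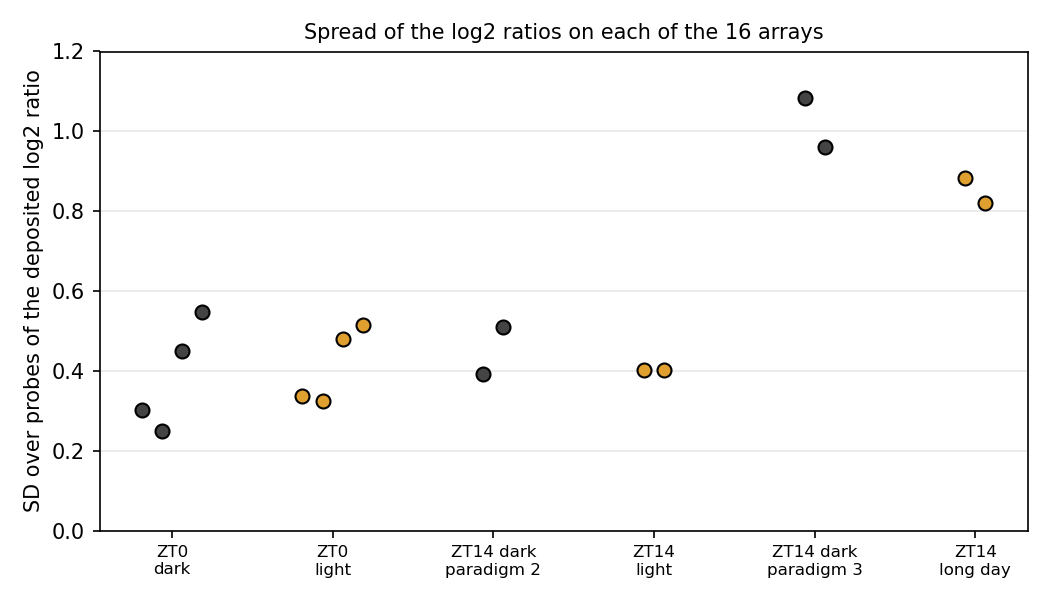
The SD over probes of the deposited log2 ratio on each of the 16 arrays (1 point per array), by group, with dark groups in grey and light groups in orange. The 4 arrays of paradigm 3 lie between 0.820 and 1.08, above the other 12, which reach at most 0.546.

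After late-night light, no single gene passed limma's test, and the 10 smallest p-values are given as values only. The brain-derived neurotrophic factor BDNF, a growth factor induced by activity in neurons, had the smallest p, with a difference of -0.91 ± 0.15 (4 pools each, adjusted p = 0.327). HSPA5, the main chaperone of the endoplasmic reticulum, had 0.75 ± 0.14 (adjusted p = 0.354). The differences were 0.91 ± 0.19 for LONRF1, 0.60 ± 0.14 for the metalloprotease MEP1A and 0.74 ± 0.17 for SH3GL2. They were -1.18 ± 0.25 for the globin HBBA, -1.12 ± 0.26 for CD40LG, -1.47 ± 0.35 for the collagenase MMP13 and -0.81 ± 0.18 for NDUFB2, a subunit of respiratory complex I. All 7 had an adjusted p of 0.642, and OLFML2B, at -0.55 ± 0.13, had 0.736. Among the clock genes, PER3 had -0.28 ± 0.27, CRY1 0.77 ± 0.69, CRY2 0.49 ± 0.20, CLOCK 0.00 ± 0.12 and BHLHE40 -0.28 ± 0.18. Within the first series of slide numbers alone CRY1 turned to -0.10. TPH1, the first enzyme on the way to melatonin, had 0.03 ± 0.16, and the immediate early gene EGR1 -0.23 ± 0.15. Adjusted over the list alone, BDNF passed among immediate early genes, NDUFB2 in oxidative phosphorylation and HBBA among erythroid markers, all 3 negative, while the lists as a whole did not.

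Camera with its preset correlation called 7 of the 26 gene lists after late-night light, and 0 with an estimated correlation. Another split of the same arrays also reached 7 lists, so chance is not excluded for them. The endoplasmic reticulum folding list was higher (adjusted p = 0.00136), with 18 of 27 members positive. HSPA5 and SDF2L1, another protein of that compartment at 0.53 ± 0.13, passed when adjusted over the list alone. With an estimated correlation the list had an adjusted p = 0.0516. Heat shock proteins were higher too, with 14 of 18 positive (adjusted p = 0.0254, and adjusted p = 0.192 with an estimated correlation), CHORDC1 leading at 0.53 ± 0.25. Cytosolic ribosomal proteins were lower, with 28 of 32 negative and RPL22 at -0.41 ± 0.16 (adjusted p = 0.0080, and adjusted p = 0.252 with an estimated correlation). Cell cycle genes were lower, with 18 of 28 negative (adjusted p = 0.0254, and adjusted p = 0.192 with an estimated correlation), among them the topoisomerase TOP2A at -0.42 ± 0.18 and the replication clamp PCNA at -0.25 ± 0.11. In the heat shock, ribosomal and cell cycle lists 0 members passed over the list alone.

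Markers of other cell types were among the lists called in the same comparison, and chance is not excluded for them either. Lymphoid markers were lower in light, with 14 of 17 negative (adjusted p = 0.000913, and adjusted p = 0.207 with an estimated correlation). The B cell receptor chain CD79B had -0.96 ± 0.33 and the T cell receptor chain CD3E -0.49 ± 0.19. Macrophage markers were lower, with 13 of 16 negative, lysozyme (LYZ) at -0.53 ± 0.20 and LAPTM5 at -0.31 ± 0.14 (adjusted p = 0.0254, and adjusted p = 0.281 with an estimated correlation). Choroid plexus markers were higher, with 5 of 5 positive, KL at 0.80 ± 0.33 and IGF2 at 0.48 ± 0.24 (adjusted p = 0.0254, and adjusted p = 0.207 with an estimated correlation). For each of these 3 lists 0 members passed over the list alone.

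For late-night light, limma called 0 of 12532 genes, and 527 had an unadjusted p under 0.05. By array number, 3 of the 8 arrays of this paradigm belong to a second slide series: limma called 0 genes with the series as a block, 0 within the first series (3 light and 2 dark pools) and 5 within the second, which holds 1 light pool and 2 dark pools.

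After early-night light, thioredoxin (TXN), a small protein that reduces disulfide bonds, was the 1 gene called by limma. Its deposited ratio was higher by 2.11 ± 0.25 on the log2 scale in light, a fold of 4.30 (2 pools each, adjusted p = 0.0138). The remaining small p-values did not pass. Simulated data gave a recovery of 13.1% for this comparison at a change of 1 on the log2 scale, so changes can be missed. MACIR had -1.53 ± 0.24 (adjusted p = 0.0749), BDNF 1.15 ± 0.21 and the splicing factor TRA2B 0.99 ± 0.18 (both adjusted p = 0.171). IRAK4, a kinase of Toll-like receptor signalling, had 1.08 ± 0.21 (adjusted p = 0.194), LONRF1 -1.36 ± 0.27 and ISLR 1.07 ± 0.21 (both adjusted p = 0.252). The amino acid transporter SLC38A2 had -1.24 ± 0.26, SLC47A2 1.33 ± 0.28, and SNAPC5 -1.68 ± 0.35 (all adjusted p = 0.258), and the probes of SNAPC5 disagreed in sign. Without dark pool 1 SNAPC5 had -0.97, and with all 4 ZT14 dark pools as controls -0.29. PER3 had 0.14 ± 0.38, CRY1 -0.76 ± 0.97, CRY2 0.30 ± 0.28, CLOCK -0.46 ± 0.18, BHLHE40 0.08 ± 0.25, TPH1 0.14 ± 0.23 and EGR1 -0.17 ± 0.21.

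The phototransduction list was higher after early-night light, with 5 of 5 measured members positive (camera, adjusted p = 0.00947, and adjusted p = 0.119 with an estimated correlation). Only 5 of its 45 listed genes were measured, so the list does not show whether phototransduction genes as a whole changed. The opsin-like RGR had 0.86 ± 0.36, the retinoid transporter ABCA4 0.39 ± 0.18, RLBP1 0.32 ± 0.25, GNB1 0.29 ± 0.18 and RGS9 0.28 ± 0.41, and 0 passed over the list alone. Oxidative phosphorylation genes were higher, with 21 of 32 positive (adjusted p = 0.0484, and adjusted p = 0.605 with an estimated correlation). In that list NDUFB2, at 1.17 ± 0.26, and ATP5J2, at 0.81 ± 0.20, passed when adjusted over the list alone. Of 21 immediate early genes, BDNF and SIK1, at 0.76 ± 0.20, passed over the list alone, and the list as a whole did not. The folding enzyme PDIA3, at -0.80 ± 0.18, and the choroid plexus and ependyma marker DNAH9, at 0.91 ± 0.23, did so too in lists that did not pass. Limma called 1 of 12532 genes for early-night light, and 526 had an unadjusted p under 0.05. The call of TXN ended with only the 4 arrays compared (adjusted p = 0.883), with a prior with trend and robust fitting (adjusted p = 0.0716) and without early-night light pool 1 (adjusted p = 0.106).

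In the long day, limma called 369 genes, 186 higher and 183 lower, of which 210 had a symbol. With array weights, after quantile normalization or after scaling each array it called 0, so the genes below depend on the main fit. The phosphatidylserine receptor TIMD4 was higher by 3.54 ± 0.47 (2 pools each, adjusted p = 0.00362), UBXN2A by 2.72 ± 0.42, INSIG1, which holds back sterol synthesis, by 2.63 ± 0.36, and the homeobox gene MSX1 by 2.60 ± 0.39. SUSD2 was at 2.59 ± 0.47, CHSY3 at 2.47 ± 0.44, HYI at 2.44 ± 0.42 and RARRES1 at 2.37 ± 0.48. The ubiquitin ligase RNF5 was lower, at -3.71 ± 0.88 (adjusted p = 0.0408), as were HMCES at -2.88 ± 0.42, ANO3 at -2.64 ± 0.31 and the signalling protein WNT11 at -2.41 ± 0.47. CCDC113 was at -2.22 ± 0.25, TOR4A at -2.15 ± 0.24, myoglobin (MB) at -2.06 ± 0.49 and GCHFR, the feedback regulator of GCH1, at -2.02 ± 0.32. The pools of the dark controls had -0.32 and 4.00 for RNF5, which moved to -1.55 without pool 4 and to -5.87 without pool 3. Without long-day pool 1, WNT11 had -1.50 and MB -1.36, and without dark pool 4 RARRES1 had 1.34.

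Members of several gene lists were among the genes called for the long day. Of 21 immediate early genes, BDNF was higher by 0.89 ± 0.21 and SIK1, a kinase induced by cAMP, by 0.82 ± 0.20. Of 9 clock genes, CSNK1D, a kinase of the PER proteins, was lower at -1.65 ± 0.36. PTS, an enzyme that makes the cofactor of tryptophan hydroxylase, was higher by 1.29 ± 0.30. The transcription factors NEUROD1, at -1.67 ± 0.41, and ATF1, at -0.88 ± 0.20, were lower, as were the co-chaperone DNAJB6 at -1.66 ± 0.39 and NUSAP1 at -0.98 ± 0.21. SEC23B was higher by 1.38 ± 0.34 and RPL8 by 0.94 ± 0.23. Among markers of other cell types, the endothelial receptor KDR was higher by 2.36 ± 0.53 and the pericyte gene RGS5 lower at -1.64 ± 0.34. The calls of KDR (1.17 without dark pool 3), DNAJB6 and NEUROD1 (-0.83 and -0.94 without dark pool 4), PTS (0.86 without long-day pool 1) and SEC23B (0.86 without long-day pool 2) ended without those pools. Of the 28 genes named here and above that passed, 16 lost the call without at least 1 pool. All 28 lost it with array weights, after quantile normalization and after scaling. CRY1 had -2.42 ± 0.97 and did not pass (adjusted p = 0.204), nor did CRY2 at -0.76 ± 0.28, PER3 at -0.44 ± 0.38, CLOCK at 0.15 ± 0.18, BHLHE40 at -0.23 ± 0.25, TPH1 at 0.18 ± 0.23 and EGR1 at -0.10 ± 0.21. For CRY1, dark pools 3 and 4 had 1.18 and 3.44, and the difference ran from -3.55 to -1.16 across alternatives. Adjusted over the list alone but not over all genes, CCN2, QDPR, RPL12, MCM3, KIF20A and LUM passed with positive and SEL1L, FDFT1, SYN2 and EGFL7 with negative differences. Camera called 0 of 26 lists, and the lowest adjusted p was 0.370, for oxidative phosphorylation.

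Limma called 369 of 12532 genes for the long day, and 2232 had an unadjusted p under 0.05. On simulated data without any change it called 124.2 on average and 188 at most. It called 0 genes with array weights, 0 with only the 4 arrays compared, 0 after quantile normalization and 0 after scaling each array to 1 SD.

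Taking both ZT14 paradigms together, limma called 37 genes for light at ZT14, 19 higher and 18 lower, and 23 of them had a symbol. TXN was higher by 1.86 ± 0.18 (4 pools each, adjusted p = 0.00104), and MACIR was lower at -1.41 ± 0.17 (adjusted p = 0.00643). BDNF was higher by 1.02 ± 0.15 (adjusted p = 0.0299), PROCR, the endothelial receptor of protein C, by 1.12 ± 0.15, NDUFB2 by 1.07 ± 0.18, IRAK4 by 0.82 ± 0.15 and SIK1 by 0.79 ± 0.14. RGS5 was lower at -1.29 ± 0.24, SPTSSB, a subunit of serine palmitoyltransferase, at -1.07 ± 0.18 and LONRF1 at -1.04 ± 0.19. These 10 genes and 3 unnamed probes had 1 sign and an unadjusted p under 0.05 in each paradigm, and 32 of the 37 had 1 sign in both. The 37 were called on the mean of both paradigms, so this agreement is favoured by the choice and is not a replication. By limma, 37 had an unadjusted p under 0.05 in the long day and 13 in early-night light. Single pools carried part of the agreement. In early-night light RGS5 had -0.93, and -0.28 without dark pool 2, while SPTSSB had -0.70, and -0.44 without light pool 2. In the long day LONRF1 had -0.72, and -0.21 without dark pool 3, while DT40subNB_2A8 had -1.33, and -0.82 without long-day pool 1. For others the long day supplied most of the difference: INSIG1, at 1.42 ± 0.26 in the mean, had 0.22 ± 0.36 in early-night light and 2.63 ± 0.36 in the long day. The same holds for NRDE2 at 1.11 ± 0.18, ARSH at 0.90 ± 0.16, GPR146 at -0.94 ± 0.17 and NECTIN3 at -0.79 ± 0.14.

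**Figure D2:**
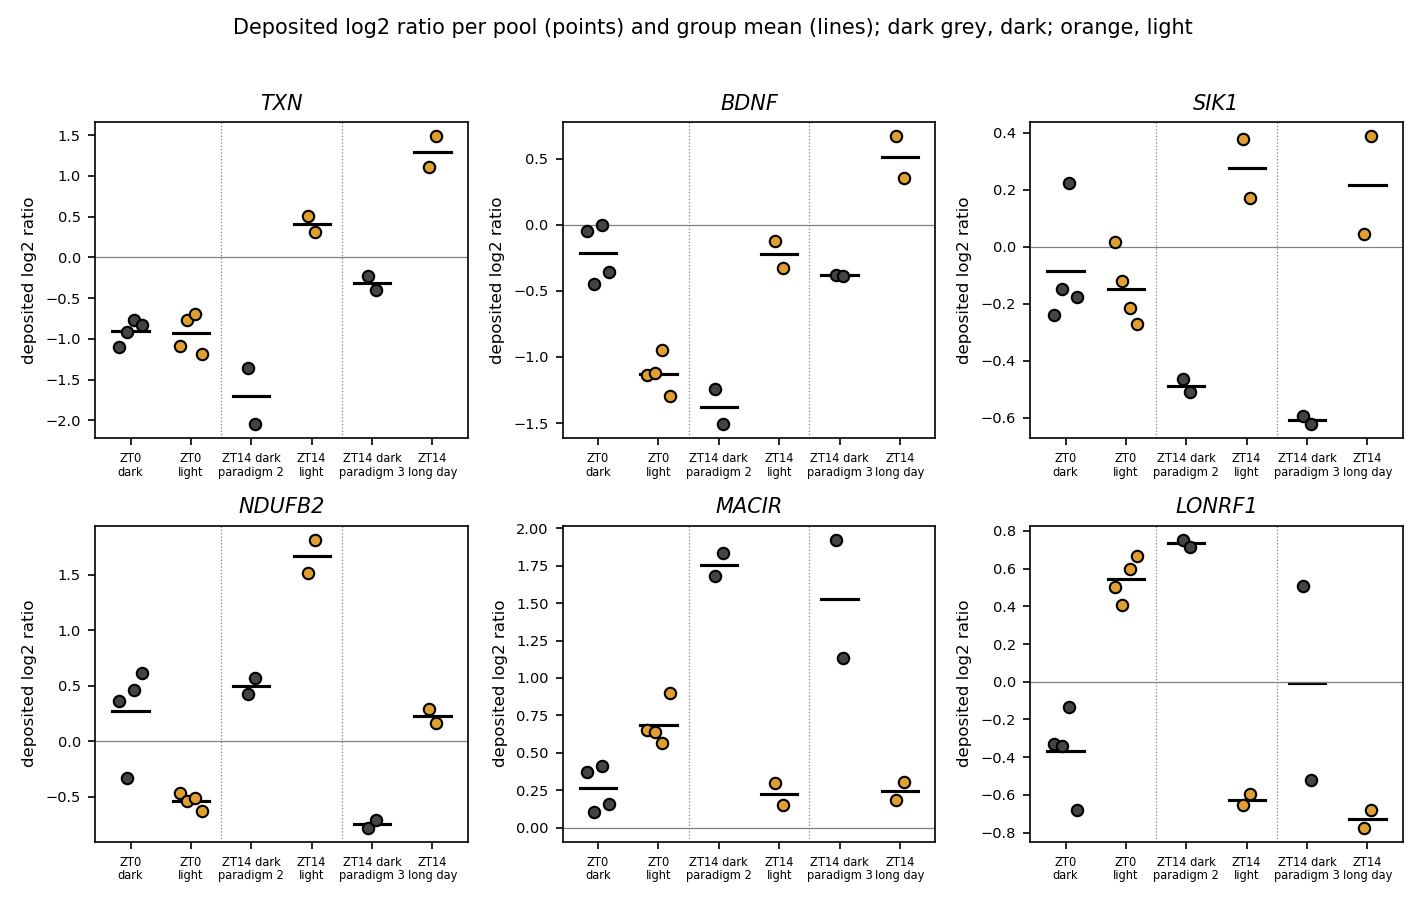
The deposited log2 ratio (vertical axis) of 6 genes in every pool (points) with the group mean (lines), for the 6 groups, dark in grey and light in orange. TXN, BDNF, SIK1 and NDUFB2 lie higher, and MACIR and LONRF1 lower, in light than in the dark controls of the same paradigm at ZT14, while at ZT0 the difference is -0.91 for BDNF and 0.91 for LONRF1.

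Oxidative phosphorylation genes were higher with light at ZT14, with 27 of 32 positive (camera, adjusted p = 0.0154, and adjusted p = 0.576 with an estimated correlation). NDUFB2 was the 1 member that passed, over all genes and over the list alone. Of 21 immediate early genes, BDNF and SIK1 passed over all genes and over the list alone, and the list as a whole did not. Adjusted over the list alone but not over all genes, PTS, QDPR and CAMK2D passed with positive and CSNK1D, ATF1, NEUROD1, FDFT1 and MB with negative differences. The following did not pass: CRY1 had -1.59 ± 0.69, CRY2 -0.23 ± 0.20, PER3 -0.15 ± 0.27, CLOCK -0.16 ± 0.12 and BHLHE40 -0.08 ± 0.18. TPH1 had 0.16 ± 0.16 and EGR1 -0.14 ± 0.15. Limma called 37 of 12532 genes, and 1538 had an unadjusted p under 0.05. In simulated data with 200 changed genes it made 43.6 false calls on average at a change of 1, and 60 at a change of 2. The count was 2 with array weights, 1 with trend and robust fitting, 1 after scaling, 0 after quantile normalization, 8 without early-night light pool 1 and 639 without pool 4 of the paradigm 3 dark controls.

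Across all 12532 genes the light effects of the 3 paradigms were hardly related. Pearson's r was 0.0495 and Spearman's rho 0.0655 between early-night light and the long day. They were -0.0389 and -0.0542 between late-night and early-night light, and 0.0107 and 0.00788 between late-night light and the long day. TXN was the 1 gene called both for early-night light and for the long day, where it was higher by 1.61 ± 0.25. At an unadjusted p under 0.05 in both, 94 genes were shared against 93.7 under independence, and 63 of them had 1 sign.

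**Figure D3:**
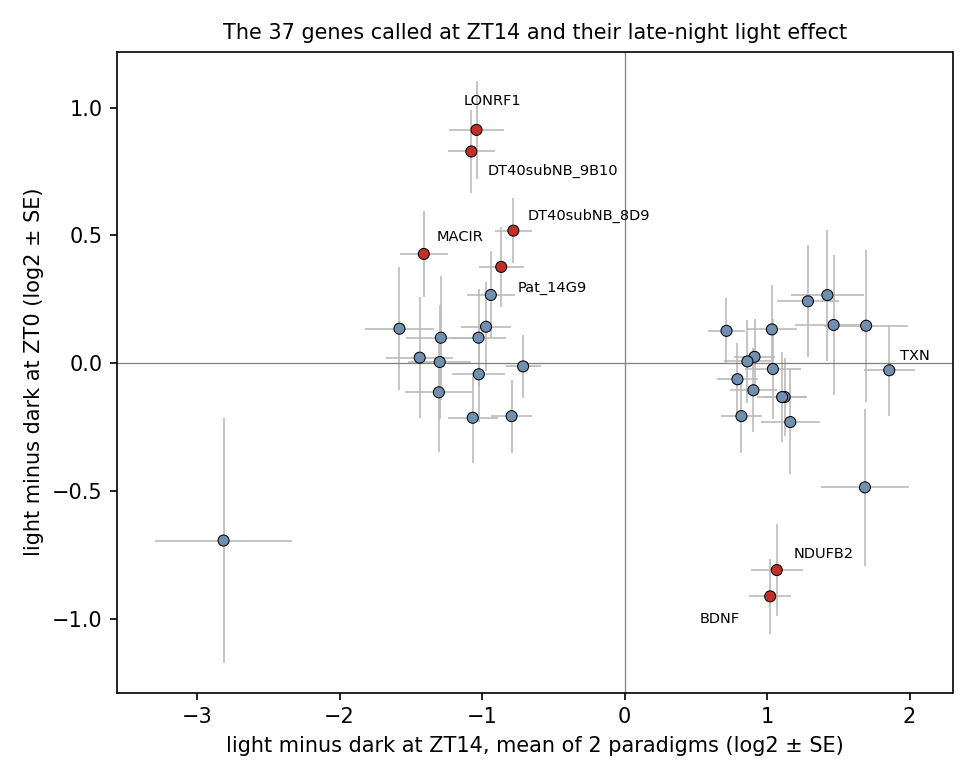
The 37 genes called for light at ZT14: the difference at ZT14 (horizontal, mean of 2 paradigms) against the difference after late-night light (vertical), log2 ± SE, with red points for an unadjusted p under 0.05 after late-night light. All 7 red points lie on opposite sides in the 2 comparisons, among them BDNF at 1.02 and -0.91 and LONRF1 at -1.04 and 0.91.

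Tests of the difference between light effects singled out a few of the same names. Late-night minus early-night light differed for 5 genes: LONRF1 at 2.27 ± 0.33, the unnamed probe DT40subNB_9B10 at 2.13 ± 0.28, MACIR at 1.96 ± 0.29, TXN at -2.13 ± 0.31 and BDNF at -2.06 ± 0.26. The long day minus early-night light differed for 3: TOR4A at -2.92 ± 0.34, the unnamed probe DT40subNB_18F2 at -2.53 ± 0.37 and CCDC113 at -2.50 ± 0.35. An unadjusted p under 0.05 was found for 516 and 1320 genes. Limma called 0 for the first difference with trend and robust fitting and without any 1 of late-night light pools 2 and 4 and ZT0 dark pools 1 and 3. It called 0 for the other with array weights, after quantile normalization, after scaling and with only the arrays compared.

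At ZT0, compared with ZT14, 2385 genes differed between dark controls (ZT0 minus the mean of both ZT14 groups, 4 pools each), 1079 higher and 1306 lower. Among 9 clock genes, the circadian repressors PER3, at -1.16 ± 0.27 (adjusted p = 0.00997), and CRY1, at -2.42 ± 0.69, were lower at ZT0, as was the nuclear receptor RORA at -0.63 ± 0.16. CSNK1E, which phosphorylates PER proteins, was higher by 1.42 ± 0.27. CLOCK had -0.08 ± 0.12, CRY2 -0.41 ± 0.20 and BHLHE40 -0.10 ± 0.18, its probes disagreeing in sign, and these did not pass. CRY1 had -1.15 with the paradigm 2 controls alone (adjusted p = 0.664) and -3.68 with the paradigm 3 controls alone, and PER3 -1.64 (adjusted p = 0.111) and -0.69 (adjusted p = 0.125). For CRY1, ZT0 dark pools 1 to 4 had -0.21, -0.0050, -2.83 and -2.46. By array number, pools 1 and 2 are in the first slide series and pools 3 and 4 in the second. With the paradigm 2 controls alone CSNK1E turned to -0.019 and CRY2 to 0.31, while CRY2 had -1.12 with the paradigm 3 controls alone. By limma, CRY2 passed in 1 of the alternatives (adjusted p = 0.00334). After quantile normalization PER3 turned to 0.052. The clock list as a whole did not pass (adjusted p = 0.501).

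The melatonin synthesis list was higher at ZT0, with 6 of 7 positive (camera, adjusted p = 0.0200, and adjusted p = 0.274 with an estimated correlation). Only 7 of its 15 listed genes were measured. The listed enzymes AANAT and ASMT were not tested under their symbols, so the list does not show whether melatonin synthesis as a whole changed. Its called members included enzymes that make or recycle tetrahydrobiopterin, the cofactor of tryptophan hydroxylase. PTS was higher by 1.20 ± 0.21, QDPR by 1.05 ± 0.17 and GCH1 by 0.87 ± 0.24. AHCY, which removes the by-product of methylation, was higher by 1.28 ± 0.40. TPH1 itself was lower, at -0.51 ± 0.16 (adjusted p = 0.0463). Adjusted over the list alone, 5 were higher and 1 lower. With the paradigm 2 controls alone QDPR turned to -0.12, PTS had 0.31, GCH1 0.46, AHCY 0.76 and TPH1 -0.58. All 7 members were lower in the ZT14 controls of paradigm 3 than in those of paradigm 2, where camera, run after the data were seen, gave an adjusted p = 0.0441 (adjusted p = 0.234 with an estimated correlation).

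Genes of the respiratory chain and of the ribosome were higher at ZT0. Of 32 oxidative phosphorylation genes 28 were positive and 7 passed, 8 when adjusted over the list alone (adjusted p = 0.00251, and adjusted p = 0.339 with an estimated correlation). They included UQCRFS1 of complex III at 1.68 ± 0.24, ATP5L of ATP synthase at 1.52 ± 0.26, and NDUFA10 at 1.41 ± 0.24 and NDUFV1 at 1.35 ± 0.27 of complex I. Of 32 ribosomal proteins 24 were positive and 6 passed, 5 when adjusted over the list alone (adjusted p = 0.0126, and adjusted p = 0.598 with an estimated correlation). RPS23 was at 1.26 ± 0.28, RPL12 at 0.82 ± 0.19, RPL32 at 0.81 ± 0.18 and RPL8 at 0.81 ± 0.16. Of the glycolysis list HK1, at 0.82 ± 0.14, and PDK4, a kinase that restrains pyruvate dehydrogenase, at 1.06 ± 0.19, were higher. With the paradigm 2 controls alone the genes named here were positive but smaller: UQCRFS1 had 0.89, NDUFV1 0.22, RPL8 0.21 and HK1 0.13. With the paradigm 3 controls alone these 4 had 2.48, 2.48, 1.42 and 1.52. In the comparison of ZT0 with ZT14 the control spots had a median difference of 0.51, while the median of the oxidative phosphorylation and of the ribosomal list was 0.22.

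Signalling and folding genes went both ways between ZT0 and ZT14. Of 23 cAMP and calcium genes 3 were higher and 4 lower: the peptide ADCYAP1 was at 1.22 ± 0.29, PDE1C at 1.22 ± 0.29, CAMK2D at 1.03 ± 0.21 and the calcium channel RYR3 at -0.99 ± 0.19. Of 21 immediate early genes 4 were higher: CCN2 by 1.16 ± 0.34, BDNF by 0.67 ± 0.15, KLF9 by 0.55 ± 0.17 and SIK1 by 0.46 ± 0.14. Of 27 folding genes, SEC23B at 1.18 ± 0.24 and ERP44 at 0.99 ± 0.17 were higher, and 5 were lower, among them TXNDC11 at -0.97 ± 0.30 and SEL1L at -0.94 ± 0.30. DNAJA2 was at 1.99 ± 0.40, DNAJB4 at -1.15 ± 0.20 and CHORDC1 at -1.16 ± 0.25. INSIG1 was at 1.54 ± 0.26, GGPS1 at 1.06 ± 0.30, SQLE at -0.55 ± 0.17 and ELOVL6 at 0.84 ± 0.25. CDC20 was at 1.28 ± 0.32, MCM3 at 0.72 ± 0.16 and the antiviral MX1 at -1.20 ± 0.33. EGR1 had -0.08 ± 0.15 and did not pass. With the paradigm 2 controls alone SEC23B had 0.011, CCN2 0.040 and CAMK2D 0.086, while BDNF had 1.16 there and 0.17 with the paradigm 3 controls alone. Without pool 3 of the paradigm 3 dark controls CCN2 had 0.75, PDE1C 0.79 and TXNDC11 -0.54, and without pool 4 SEL1L had -0.46 and ELOVL6 0.55.

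Among the called genes with a symbol and no overlap between ZT0 and ZT14 pools, the 8 largest differences in each direction were the following. UBXN2A was higher by 2.51 ± 0.30, FAM129B by 2.50 ± 0.56, TADA2A by 2.45 ± 0.34, the cholecystokinin receptor CCKAR by 2.43 ± 0.45, ZNF800 by 2.24 ± 0.30, AAK1 by 2.18 ± 0.36, SELENOS by 2.17 ± 0.29 and the desaturase SCD5 by 2.13 ± 0.35. RUNX1T1 was lower, at -3.05 ± 0.96, as were the protease CAPN3 at -2.93 ± 0.68, the vitellogenin gene VTG3 at -2.75 ± 0.82, NRAP at -2.53 ± 0.46 and SYT10 at -2.28 ± 0.68. The prokineticin receptor PROKR1 was at -2.26 ± 0.25, the nicotinic receptor subunit CHRNB4 at -2.24 ± 0.27 and KRT23 at -2.21 ± 0.56. Pools 3 and 4 of the paradigm 3 dark controls had 7.22 and 0.77 for RUNX1T1 and 5.79 and 0.97 for VTG3. Without pool 3, RUNX1T1 had -1.44 and VTG3 -1.55 (adjusted p = 0.0784), and without pool 4 KRT23 had -1.31. Markers of other cell types went both ways and none of their lists passed: DMA was at 1.09 ± 0.21, SOX9 at 1.12 ± 0.21, AQP1 at 0.87 ± 0.26, TLR7 at 0.69 ± 0.20, RGS5 at -1.31 ± 0.24, TNNT3 at -1.17 ± 0.21, P2RY13 at -0.90 ± 0.18, TFRC at -0.84 ± 0.27 and FBN1 at -0.47 ± 0.15. With the paradigm 2 controls alone P2RY13 turned to 0.10.

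Time of day and paradigm differ together in this comparison, and limma called 2385 of 12532 genes, with 4101 at an unadjusted p under 0.05. With the paradigm 3 controls alone it called 4265, and with the paradigm 2 controls alone 4: MACIR at -1.49 ± 0.20, and the unnamed probes DT40subNB_9B10 at -1.33 ± 0.20, C0004112_I23 at -1.67 ± 0.25 and C0004127_D10 at 1.67 ± 0.25. Of the 66 genes named for time of day that passed with both control groups, 63 passed with the paradigm 3 controls alone, and none with those of paradigm 2 alone, where the lowest adjusted p was 0.0511, for BDNF, and 49 lay under their size divided by 1.5 or turned. Without at least 1 pool, 23 of the 66 lost the call: AHCY, AQP1, CCN2, CDC20, CRY1, ELOVL6, FBN1, GCH1, GGPS1, KLF9, KRT23, MX1, RORA, RUNX1T1, SEL1L, SIK1, SQLE, SYT10, TFRC, TLR7, TPH1, TXNDC11 and VTG3. With the ZT0 pools divided so that no array was shared, the differences from the 2 control groups correlated at 0.293 and 0.401 across genes, which are not independent replicates. Scaling each array to 1 SD left 925 calls and quantile normalization 888.

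The ZT14 dark controls of paradigms 2 and 3, which the labels describe alike, differed in 2583 genes, 1405 higher and 1178 lower in paradigm 3. The phosphodiesterase PDE11A was higher by 3.88 ± 0.90, and the unnamed probes C0004118_L5, C0004117_G18 and C0004122_B8 by 4.82, 3.83 and 3.83. Without pool 4 of the paradigm 3 controls PDE11A had 1.84 and C0004122_B8 2.33, and without pool 3 C0004118_L5 had 2.80 and C0004117_G18 1.64 (adjusted p = 0.0648 and 0.197). An unadjusted p under 0.05 was found for 4347 genes. After scaling each array to 1 SD 29 genes were called, after quantile normalization 22, and with only the 4 arrays compared 0.

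Of the 26 lists, 10 passed in at least 1 of the 5 comparisons of light or time of day and 16 in none. The lowest adjusted p of each of those 16 over the 5 comparisons was 0.317 for the core clock, 0.511 for pineal transcription factors, 0.317 for immediate early genes and 0.667 for cAMP and calcium signalling. It was 0.363 for sterol synthesis, 0.696 for fatty acid synthesis, 0.478 for glycolysis, 0.326 for thyroid and photoperiod genes and 0.424 for the interferon response. Among other cell types it was 0.418 for erythroid cells, 0.0808 for glia, 0.609 for oligodendrocytes, 0.320 for neurons, 0.0714 for connective tissue, 0.0540 for endothelium and pericytes and 0.317 for muscle. Measured members numbered 6 for pineal transcription factors, 13 for sterol synthesis, 9 for fatty acid synthesis, 9 for thyroid and photoperiod genes, 10 for the interferon response and 5 for erythroid cells.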

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

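The comparison of late-night light with light at ZT14, and the tests of scaled arrays, of array weights, of exchanged labels, of the mean of the control spots on each array and of the correlation between long-day arrays and their controls, were chosen after the results were seen.

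The ZT14 dark controls of paradigms 2 and 3, alike by their labels, differed in 2583 genes, and long-day arrays resembled their own dark controls. Unequal noise between arrays is argued against as the source of this likeness. Long-day arrays and those of their controls correlated across genes at 0.507 or more, and noise of single arrays is not shared. The correlation does not tell how much of the count such noise supplies. Simulated independent noise gave at most 17 calls, but weighting the arrays by their noise left 757, so its part in the count stays open. The wider spread of the paradigm 3 arrays may account for much of the count, since 29 genes were called after each array was scaled to 1 SD. A difference in hybridisation or labelling does reach the control spots, since plant genes by name averaged lower on each paradigm 3 array than on any of paradigm 2 (RUBISCO -1.90 to -1.52 against -0.66 to -0.33, Cab -1.14 to -0.92 against -0.57 to -0.065). How many of the genes it accounts for stays open, with 4.83% of 145 control spots called against 20.6% of genes, between the bounds set for that test, and birds or days that differ between the paradigms were not tested.

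For the long day 369 genes were called, against 1 for early-night light, with 2 pools in each group. The tables exclude neither technical explanation that was tested. Unequal noise between arrays may supply part of the count: simulated data without any change gave 124.2 calls on average. A spread borrowed from the quieter arrays may supply more, as 0 genes were called by limma with array weights, while 2232 had an unadjusted p under 0.05 in the fit without weights. An effect of the long day itself, which the design names, stays open and untested apart from these.

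Of the 37 genes called for light at ZT14, 7 had an unadjusted p under 0.05 after late-night light, and all 7 had the opposite sign there: BDNF, LONRF1, MACIR, NDUFB2 and the unnamed probes DT40subNB_9B10, DT40subNB_8D9 and Pat_14G9. Of these, 5 passed when adjusted over the 37 genes, BDNF with an adjusted p of 0.00113. Over all genes limma called 0 for late-night light, and BDNF had an adjusted p of 0.327. The 37 were chosen with the same error estimate per gene, which favours small p-values here, so the adjustment over them is not a separate test. The slide series within paradigm 1 is argued against as the source of these signs. All 7 kept the opposite sign with the slide series as a block, and 7 did so within the first series. There BDNF had -0.82, LONRF1 0.84 and NDUFB2 -0.52, against -0.91, 0.91 and -0.81 over both series. The 7 genes were chosen by that sign, so this check bears on the series alone and not on chance. An exchange of the light and dark labels in paradigm 1 stays open: the slope of the late-night effects on the ZT14 effects over the 37 genes was -0.0644 (SE 0.0635), far from -1, but effects need not be alike at both times of day. Genes that follow a recent change of the lighting, whichever way it went, are a candidate explanation and a hypothesis: 7 and 6 genes lay on the same side in the 2 pairings of separate arrays, but these genes were chosen with the same dark pools, so the test leaves it open.

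A test of the difference singled out genes between groups. Late-night minus early-night light gave 2.27 for LONRF1, 2.13 for DT40subNB_9B10, 1.96 for MACIR, -2.13 for TXN and -2.06 for BDNF. The long day minus early-night light gave -2.92 for TOR4A, -2.53 for DT40subNB_18F2 and -2.50 for CCDC113. Late-night light minus light at ZT14 gave 9 genes: LONRF1 at 1.95, DT40subNB_9B10 at 1.90, MACIR at 1.84, C0004110_K8 at 1.39, DT40subNB_8D9 at 1.30, NDUFB2 at -1.88, TXN at -1.89, BDNF at -1.94 and C0004119_I2 at -2.23.

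One pool lay far from the other 3 of its group in 16 of 166 groups of 4 values, where chance gives about 1 in 20, or 8.3. The gap to the nearest pool over the range of the group was, in late-night light, 0.965 for SH3GL2, 0.947 for ELOVL6, 0.915 for CRY1, 0.913 for FAM129B, 0.877 for CHORDC1, 0.866 for P2RY13, 0.865 for UBXN2A, 0.859 for CLOCK, 0.857 for SQLE and 0.847 for MCM3. In the ZT0 dark controls it was 0.993 for PTS, 0.899 for RPS23, 0.894 for AHCY, 0.894 for DNAJA2, 0.894 for RPL12 and 0.857 for ADCYAP1. For CRY1, pool 4 of late-night light had -1.81 and the mean of the other 3 was -0.21. That array is in the second slide series, as are ZT0 dark pools 3 and 4, which had -2.83 and -2.46. On the paradigm 1 arrays of the first series CRY1 lay between -0.27 and -0.0050. Pool 4 of late-night light was also the distant pool for ELOVL6, CHORDC1, SQLE and MCM3.

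Other splits of the same arrays into equal groups were fitted for comparisons of 4 pools with 4, within all 16 arrays. For time of day and light at ZT14 the 8 arrays formed 2 groups there, with a term for the paradigm in the ZT14 splits that do not follow it, and the real counts lie below those of the 6-group fit. For late-night light the real count of genes was 0 (limma, 527 at an unadjusted p under 0.05; highest other 2), which 35 of 35 splits reach whatever the data, so they decide nothing. There, 3 of 35 splits gave as many lists (real 7, highest other 7), so chance is not excluded for them. For time of day, 1 of 35 splits reached the real 98 genes (highest other 0), the lowest share that 35 splits can give. Chance is less likely there but not excluded. The paradigm stays open, since the real split also divides paradigm 1 from the others. For the lists, 6 of 35 splits reached the real 2 (highest other 3). For light at ZT14, 4 of 35 splits reached the real 5 genes, and 3 of 35 the real 1 list (highest other 1), so chance is not excluded. There, the split that follows the paradigm called 4034 genes, and the next highest 19. Arrays, birds and days may all differ between the paradigms, so this count does not tell them apart. For late-night light minus light at ZT14, 1 of 70 splits reached the real 9 genes (highest other 5). That comparison was chosen after the opposite signs were seen, so the splits do not settle whether chance is excluded, and with the first slide series only limma called 0 genes (1052 at an unadjusted p under 0.05 over all arrays).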

How the results depend on the processing

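Arrays scaled to 1 SD, paradigm 3 arrays left out, the first slide series only, the slide series as a block for differences between light effects, and control spots kept were chosen after the data were seen. Centring, a fold minimum of 1.5 and a value on all 16 arrays kept every count of genes within 1.5 times. Of 1663 values of named genes for time of day under alternatives, 1285 kept their sign and side of the threshold, 362 lost the call and 1 gained it. The sign turned for 7 values of genes called in the main fit or the alternative, and for 8 values of genes called in neither. Where counts changed, the cause was not tested. With 1 pool left in a group, that pool was assumed to vary like the others. Signal over background is unknown, and the number of arrays is what limits precision.

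For late-night light (0 genes by limma, 527 at an unadjusted p under 0.05) quantile normalization called 3, array weights 2, scaled arrays 2 and slide series 2 alone 5, and leaving out 1 pool 0 to 2 (2 without dark pool 2). For early-night light (1) quantile normalization called 10, the noisiest 5th of genes left out 3, trend and robust 0, array weights 6, only the arrays compared 0, adjusted p under 0.10 3, all 4 ZT14 dark pools 392, scaled arrays 6, paradigm 3 left out 3, and leaving out 1 pool 2 to 65 (65 without dark pool 1). For the long day (369) quantile normalization, array weights, only the arrays compared and scaled arrays called 0, all 4 ZT14 dark pools 426 (158 shared), the noisiest 5th left out 635, adjusted p under 0.10 816, and leaving out 1 pool 566 to 1196 (1196 without dark pool 4, 566 without long-day pool 1).

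For time of day (2385) quantile normalization called 888 (856 shared), array weights 1502 (1449 shared), scaled arrays 925 (900 shared), paradigm 2 controls alone 4, paradigm 3 controls alone 4265, paradigm 3 left out 8, and leaving out 1 pool 1448 to 3211 (1448 without ZT0 pool 4). PER3 turned to 0.052 with quantile normalization. CSNK1E turned to -0.019, P2RY13 to 0.10 and QDPR to -0.12 with paradigm 2 controls alone and with paradigm 3 left out. For light at ZT14 (37) quantile normalization called 0, the noisiest 5th left out 134, single probes 65, trend and robust 1, array weights 2, only the arrays compared 0, adjusted p under 0.10 102, paradigm ignored 1, scaled arrays 1, and leaving out 1 pool 8 to 639 (639 without paradigm 3 dark pool 4, 8 without early-night light pool 1).

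For late-night minus early-night light (5) the noisiest 5th left out gave 10, trend and robust 0, the slide series as a block 2, and leaving out 1 pool 0 to 45 (45 without paradigm 2 dark pool 1). For the long day minus early-night light (3) quantile normalization, array weights, only the arrays compared and scaled arrays gave 0, no filter 8, control spots kept 8, the noisiest 5th left out 63, single probes 5, trend and robust 1, adjusted p under 0.10 39, and leaving out 1 pool 5 to 388 (388 without paradigm 3 dark pool 4). For the ZT14 dark controls (2583) quantile normalization gave 22, array weights 757, only the arrays compared 0, scaled arrays 29, and leaving out 1 pool 1113 to 3230 (1113 without paradigm 2 dark pool 2). For late-night light minus light at ZT14 (9) the noisiest 5th left out gave 16, single probes 14, trend and robust 3, the first slide series only 0, scaled arrays 4, and leaving out 1 pool 7 to 116 (116 without paradigm 3 dark pool 4).

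Of the gene lists, 13 were called over 5 comparisons, 8 with quantile normalization, 8 with scaled arrays, 20 at an adjusted p under 0.10, 0 with an estimated correlation, 14 with fry (5 of the 13 among them), and 7 to 15 when 1 pool was left out (7 without ZT0 dark pool 4). Pearson's r across genes between early-night light and the long day (0.0495) was 0.0230 with quantile normalization, 0.0776 with the noisiest 5th left out, 0.0217 with scaled arrays, and 0.0206 to 0.0561 when 1 pool was left out. The slope used for the direction of the ratios (-0.0314) was -0.00988 with the largest difference between group means, -0.159 with clock and melatonin genes alone, -0.0438 with centred arrays, -0.0949 with quantile normalization, -0.0571 with scaled arrays, 0.0314 with every sign turned (by construction) and 0.00844 with paradigm 3 left out.

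Pool numbers as a replicate block gave 4 genes for early-night light, 0 for late-night light and 2518 for time of day (2193 shared). The pairing check gave correlations of 0.308, 0.190, -0.000165 and 0.309 for the pools of paradigm 1 and 0.120 for pool 1 of paradigm 2. Pools with unlike numbers were not set beside them, so the check does not decide whether the numbers mark pairs. The light and dark arrays of pool 3 are in different slide series. Deviations from the group mean correlated on average at 0.179 within the second series and at -0.340 between the series. The main fit did not take the numbers as pairs. No paired analysis was possible for the long day because its dark controls carry other pool numbers.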

Other observations

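The genes described here were chosen after their values were seen. HSPA5 and SDF2L1, which passed over their list alone after late-night light, were lower in the ZT0 dark controls than in the ZT14 dark controls, at -0.88 ± 0.14 (adjusted p = 0.00169) and -0.45 ± 0.13 (adjusted p = 0.0336). The mean ratio of HSPA5 was -0.02 in the ZT0 dark controls, 0.73 after late-night light, 1.02 and 0.70 in the ZT14 dark controls of paradigms 2 and 3, 0.93 after early-night light and 0.26 in the long day. For SDF2L1 these means were -0.01, 0.52, 0.39, 0.48, 0.37 and 0.80. Both differences share the ZT0 dark pools, so they are not independent.

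BDNF had mean ratios of -0.21 in the ZT0 dark controls and -1.13 after late-night light, -1.38 in the ZT14 dark controls of paradigm 2 and -0.23 after early-night light, and -0.38 in those of paradigm 3 and 0.51 in the long day. The 145 control spots tested hold plant genes and chicken genomic DNA. Between ZT0 and ZT14 dark controls 9.66% of them were called, against 19.0% of genes, with a median difference of 0.51. Between the ZT14 dark controls 4.83% were called, against 20.6% of genes, with a median of -0.38. A difference in hybridisation or labelling was not tested as an explanation of the calls for time of day and stays open.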
